A study of Homo sapiens with 8 samples.

How the data were processed

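RNA from 8 samples of HCT116 cells was hybridised as biotin-labelled cRNA to single-colour Illumina bead arrays, per the labels' protocols. Groups were taken from the titles, with 4 samples per group. Per the file headers, the authors deposited a non-normalized table with an average intensity per probe and a detection p-value per probe and array. The values show linear intensities without background subtraction (no value below 36.6) and detection p-values in steps of 1 in 770, the number of negative control beads that this implies. The control beads themselves were not used here. A second deposited table holds values on a log2-like scale that the authors had processed, with no scale, centring or method stated. Its 8 columns hold the same sorted values (largest difference 0.000564, median 7.55 in each column), as quantile normalization gives. It holds the 20045 probes with a detection p under 0.01 on at least 1 array and no other. Set against log2 of each array's own intensity, its slope was 0.526 among the dimmest probes and 1.00 among the brightest. The exact transform of that table stays unknown, the values are not centred per gene, and higher values mean higher intensity. The software that made either table is not given in the sources used here.

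Intensities were background-corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the background mean and SD of each array inferred from the detection p-values, an offset of 16 was added, and arrays were quantile normalized on the log2 scale. A probe was tested when its detection p was under 0.05 on at least 4 of the 8 arrays, which left 19755 of 47320 probes. Probes were named through the platform annotation supplied with the data, with symbols updated through RefSeq gene tables. Of the probes in the authors' table, 15374 had 1 gene name and 4671 were not named here, 3 of them because they had several names; probes outside that table were unnamed. Of the tested probes 14758 had a name, covering 11132 genes, and 4997 had none; 76 of the unnamed probes passed (52 higher, 24 lower) and are not analysed here. A gene was represented by its brightest tested probe.

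Overexpression minus control was tested with lmFit and eBayes (2-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 24 lists, of 27 fixed. Of the 7 lists past 0.05, 1 also passed with an estimated correlation (the interferon-stimulated list), and 6 passed in fry, which tests whether a list's genes move on balance in 1 direction; the histone list did not (adjusted p = 0.0697). A gene undetected on all arrays of a group has only a bound: the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the lowest signal among detected probes and the gene's own value.

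The design, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule names CACYBP, the 15 genes with the largest rises and the 15 with the largest falls among those past 0.05 whose groups do not overlap, up to 4 members per list with the smallest p, any member past 0.05 in a list that passed, and GAPDH, ACTB and EPCAM as references. Symbols of the fixed lists that had since been renamed were matched through RefSeq synonyms. This was done after a first look at the results, when no histone gene had matched under its older symbol, and it added the histone list to the lists past the threshold.

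The alternatives were no background correction, normexp with an offset of 50, median scaling, cyclic loess, the authors' table, other filters on dim probes, the replicate number as a block, array weights, another variance model, other thresholds and set tests, and each array left out in turn. Fits without overexpression replicates 1 and 3, and with the mean of RNAs without a poly(A) tail as a covariate, were added after seeing the data. No scaling moved the median difference of all tested probes, -0.03, by more than 0.1 on the log2 scale. No 2 arrays shared more than 0.00211% of their values. Correlations across arrays used deviations from group means and all 576 exchanges within groups (2-sided).

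The procedure was tested on simulated intensities of overexpression against control with known changes, over 23118 tested probes. It recovered 20% of 50 probes planted at a log2 difference of 0.5, 90% at 1, and 100% at 2 and at 4. All planted changes of 0.5 and 2 were rises and all of 1 and 4 were falls. Size and direction therefore cannot be told apart in these shares. These probes were drawn from those with a brighter background-corrected control signal, so recovery among dim probes was not tested. Of the 171 calls in the simulation 10 were false (5.85%), and the planted list was the 1 list called. Noise was drawn independently for each probe, so the simulation does not show how often camera falsely calls lists of correlated genes. Background noise was drawn on top of the spread fitted to the data, and more probes passed the filter than in the data (23118 against 19755). The shares recovered and falsely called therefore need not hold for the data. At a planted fall of 4 the median size of the estimate was 3.13, so large falls can be understated. No rise above 2 was planted, so the simulation does not show how well larger rises are estimated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.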

Results

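HCT116, an established human colon carcinoma line, was transfected with a FLAG expression plasmid that carried CacyBP/SIP or with the same plasmid without it, and RNA was isolated the day after. CacyBP/SIP, the product of CACYBP, is a calcyclin-binding protein that also binds the ubiquitin ligase Siah-1 and takes part in the turnover of beta-catenin. Expression was read on 8 single-colour Illumina bead arrays, 4 control and 4 labelled overexpression, with 47320 probes each. Between 19283 and 20816 probes were detected per array (40.8% to 44.0%). Mean intensity lay between 341 and 363 in the control arrays, while it was 309, 319, 457 and 326 in overexpression replicates 1 to 4, with replicate 3 the brightest of the 8. Over the 19755 probes tested, log2 values correlated across probes at r = 0.984 to 0.994 within groups and 0.974 to 0.987 between groups; probes are not independent replicates. The labels do not say whether the 4 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. No coordinates are given, because the genome build of the array design is not given in the sources used here.

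The question addressed was how a raised CacyBP/SIP level alters gene expression, and the target was examined first. CACYBP mRNA was not higher in the samples labelled overexpression. Its brighter probe, ILMN_1726574, read 10.72 ± 0.22 in control and 10.54 ± 0.16 in the samples labelled overexpression (log2 intensity, SD, n = 4), a difference of -0.19 (SE 0.13, 95% confidence interval -0.46 to 0.09). This is a ratio of 0.879 (0.725 to 1.07; limma adjusted p = 0.549). The dimmer probe, ILMN_1705141, differed by -0.33 (SE 0.16, adjusted p = 0.367). Where these probes lie on the transcript is not given in the sources used here, so it is open whether they can read an mRNA made from the plasmid, which need not carry the untranslated regions. The arrays therefore do not check the label, and every direction in the text is that of the samples labelled overexpression relative to control.

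The samples labelled overexpression had far higher levels of interferon genes and of genes that interferon induces. IFNL1, which encodes a type III interferon, was at least 52.7-fold higher by its brighter probe (adjusted p = 9.03e-09). Its other probe, detected on 1 of 4 control arrays, differed by 4.41 on the log2 scale (SE 0.28, adjusted p = 9.98e-07). IFNB1, which encodes interferon beta, was at least 19.7-fold higher (adjusted p = 1.13e-07). IFIT2 rose 52.7-fold (log2 difference 5.72, SE 0.19, adjusted p = 4.8e-09) and IFIT1 38.7-fold (5.27, SE 0.17, adjusted p = 4.8e-09); both encode proteins that bind viral RNA. No gene fell by a comparable amount. The largest fall was that of the pseudogene NACA4P, by 1.51 on the log2 scale (SE 0.16, adjusted p = 0.000134).

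**Figure D1:**
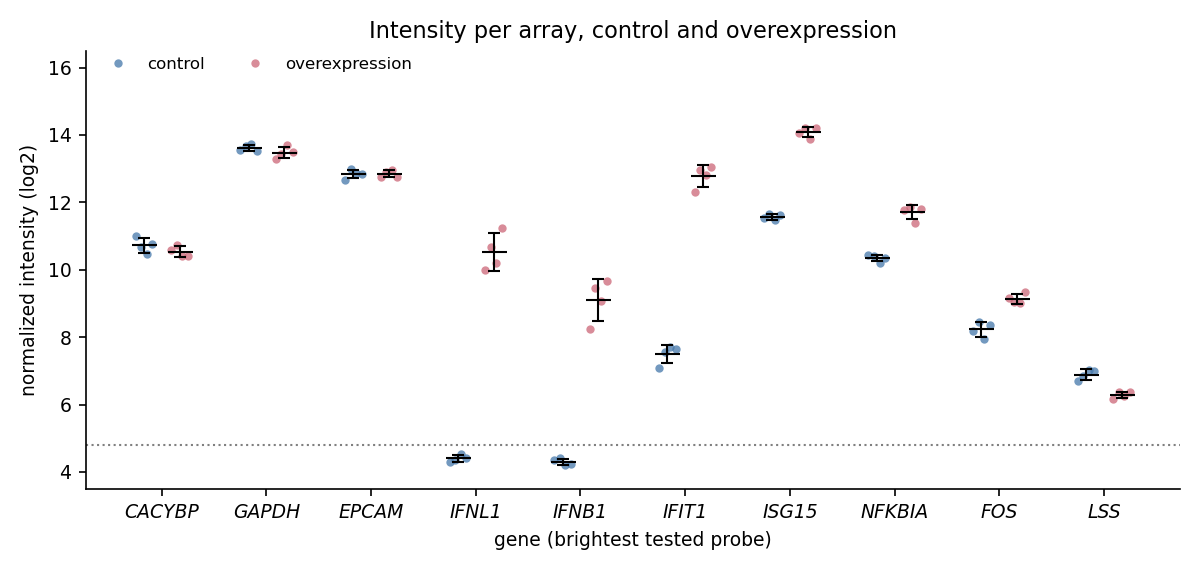
Normalized log2 intensity (vertical axis) of 10 genes in each of the 4 control and 4 overexpression arrays, with 1 point per array and black bars for mean and SD. The dotted line is the mean over arrays of the lowest signal among detected probes; IFNL1 and IFNB1 lay below it in all control arrays, IFIT1 went from 7.50 to 12.78, and CACYBP read 10.72 and 10.54.

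Over all probes, 418 passed an adjusted p of 0.05 in limma, 331 of them higher and 87 lower (79.2% higher). Counting each gene by its brightest tested probe, 224 of 11132 genes were higher and 44 lower. The 4 values of each group did not overlap for 219 of the higher and all 44 of the lower genes, where chance alone gives this for 2.86% of unchanged genes. That share holds for genes not selected by a test, so the separation of genes already selected by limma adds little evidence. At least 4-fold differences were found for 40 of the higher genes, and 1 of the lower genes fell at least 2-fold. These counts depended on the arrays used. Leaving out 1 control array in turn left 289 to 309 probes past the threshold. Without overexpression replicates 1, 2 and 4 in turn, 351, 263 and 277 passed. Only the fit without overexpression replicate 3 passed more, with 724 probes, 338 genes higher and 122 lower. The genes lower were 12 to 26 when any other array was left out. In the authors' value table the split was 335 probes higher and 198 lower (62.9% higher).

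The 15 genes with the largest rises were IFNL1, IFI27, IFIT2, IFNL2, IFIT1, OASL, IFNB1, IFITM1, IFIT3, IFI44, IFNL3, EPSTI1, IFI6, CCL5 and SAMD9. IFI27 went from 5.34 ± 0.47 to 11.39 ± 0.66 (log2 intensity, SD, n = 4), a rise of 66.4-fold. CCL5, a chemokine that attracts T cells, rose 15.4-fold (log2 difference 3.95, SE 0.20, adjusted p = 1.18e-07). The probes of IFNL1, IFNB1, IFNL2 and IFNL3 used here were not above background on any control array and were detected on all 4 arrays labelled overexpression, so their folds are lower bounds under the processing used; for IFNL1 this holds for the brighter probe only. The sizes depend on the processing: the median fitted log2 difference of these 4 genes was 5.24, against 3.92 without background correction, 3.77 with an offset of 50 and 2.94 in the authors' value table, and all 4 rose each time. IFNL2 was at least 36.9-fold and IFNL3 at least 12.6-fold higher; these are near-identical copies whose probes may read both, so their separate values are uncertain.

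Of the list of interferon-stimulated genes, 30 of 31 tested members rose, and the count was 30 when adjusted over the list alone. The median log2 difference was 2.80, or 6.98-fold. The list passed in camera (adjusted p = 1.93e-90) and also at adjusted p = 0.0224 with an estimated correlation. ISG15, a ubiquitin-like modifier, rose 5.73-fold, and HERC5, the ligase that attaches it, rose 8.72-fold. OAS3, which makes the activator of RNase L, rose 6.56-fold, and IRF7 and IRF9, transcription factors of the interferon response, rose 7.12-fold and 5.13-fold. IFIH1, a sensor of double-stranded RNA, rose by 3.46 on the log2 scale, and RIGI, another RNA sensor, was at least 5.48-fold higher. Of IFI44L, at least 2.93-fold higher by its brighter probe, a further probe differed by 0.11 (adjusted p = 0.716). XAF1, chosen after its values were seen as the remaining member, differed by 0.24 and did not pass.

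**Figure D2:**
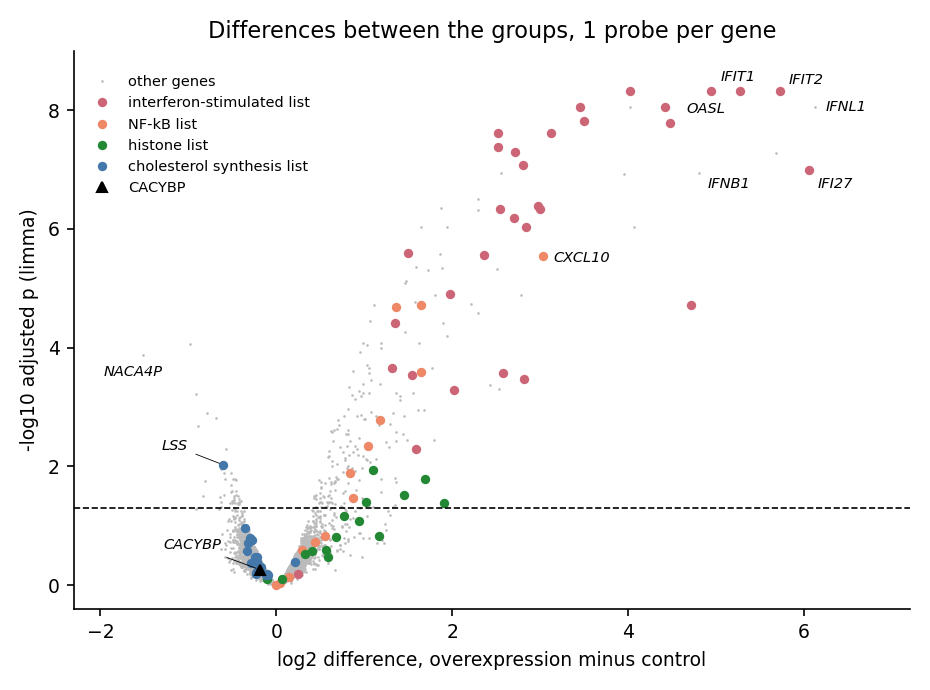
Log2 difference between overexpression and control (horizontal axis) against minus log10 of the limma adjusted p (vertical axis), with 1 point per gene (11132 genes) and 4 gene lists in colour; the dashed line marks an adjusted p of 0.05. Members of the interferon-stimulated list (red) reach 6.05 for IFI27, LSS of the cholesterol synthesis list (blue) lies at -0.60, and CACYBP (black triangle) lies at -0.19, below the line.

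Of the list of NF-kB and inflammatory targets, 8 of 14 tested members rose, and 11 did when adjusted over the list alone. The median log2 difference was 0.85, or 0.72 with IL32 at its bound. CXCL10, a chemokine that interferon also induces, rose 8.18-fold (SE 0.21 on the log2 scale, adjusted p = 2.86e-06) and was detected on 1 of 4 control arrays. CXCL1 and CXCL2, which attract neutrophils, rose 3.12-fold and 3.13-fold. NFKBIA and TNFAIP3, inhibitors of the NF-kB pathway, rose 2.58-fold and 2.26-fold. The remaining members past the threshold were CCL20, RELB and IL32, of which RELB lost the call without 7 of the 8 arrays in turn. The list passed in camera (adjusted p = 3.94e-15), but its call was lost at adjusted p = 0.0883 with an estimated correlation.

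Of the list of immediate early and feedback genes of the MAPK/ERK pathway, 8 of 23 tested members rose. Adjusted over the list alone, 10 rose and 1 fell. The median log2 difference was 0.21. The transcription factors EGR3 (2.65-fold), FOS (1.88-fold), FOSB (1.83-fold), EGR1 (1.75-fold), JUN (1.67-fold) and JUNB (1.49-fold) rose, as did SPRY2 and DUSP1, inhibitors of the pathway (each 1.55-fold). EGR3 was detected on 1 of 4 control arrays. JUN, JUNB and DUSP1 each lost the call without 6 of the 8 arrays in turn, and 5 members rose without control replicates 2 and 3 and without overexpression replicates 1, 2 and 4, each in turn, while 10 rose without overexpression replicate 3. The camera call (adjusted p = 9.05e-07) was lost at adjusted p = 0.0883 with an estimated correlation. Of the list of SRF and YAP targets, 2 of 16 rose, and 4 rose and 1 fell when adjusted over the list alone. These were THBS1, an adhesive glycoprotein (log2 difference 0.97, SE 0.18, adjusted p = 0.0106), and CCN2, a matricellular growth factor (0.81, SE 0.12, adjusted p = 0.00247), whose further probe did not pass (0.65, adjusted p = 0.0876). That list's median was 0.13, and its camera call (adjusted p = 0.0049) was lost at adjusted p = 0.101 with an estimated correlation.

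Part of the histone list rose as well. Of 15 tested members of the histone list, 5 rose, and 12 did when adjusted over the list alone, with a median log2 difference of 0.77. These were H4C8 (log2 difference 1.90, SE 0.43), H2AC18 (1.69, SE 0.32), H1-2 (1.46, SE 0.31), H2AC6 (1.10, SE 0.20) and H2AC20 (1.01, SE 0.23), with adjusted p between 0.0117 and 0.0418; H4C8 was detected on 3 of 4 control arrays. The camera call (adjusted p = 4.51e-10) was lost at adjusted p = 0.218 with an estimated correlation. The number of histone genes that rose was 12 without overexpression replicate 3, and 1 or 2 without any other array. It also hung on the processing, with 0 when dim probes were not filtered, 1 with trend and robust variance, 3 in the authors' value table, 9 with array weights and 10 with the replicate block. The median was 0.50 with an offset of 50 and 0.33 in the authors' value table. Of 146 small and structural RNAs that lack a poly(A) tail, as most of these histone mRNAs do, 8 rose, among them RNU4-2 by 1.44 on the log2 scale, and 18 rose and 1 fell when adjusted over the group alone. Their median log2 difference was 0.03, and the group's camera call (adjusted p = 0.00837) was lost at adjusted p = 0.522 with an estimated correlation. That median lay between -0.03 and 0.09 when 1 array was left out, so its sign is uncertain. Of these RNAs 23 rose without overexpression replicate 3 and 2 to 6 without any other array, 24 with the replicate block, 16 with array weights, 4 with trend and robust variance and 2 when dim probes were not filtered. That group was chosen after its values were seen. Its members moved unlike, which the median hides. RNU4-1, SNORD3A, RN7SK and RNU1-1 differed by 1.43, 1.37, 1.27 and 1.24, though RN7SK and RNU1-1 did not pass. RNU6-1 and RN7SL1 differed by 0.44 and 0.19, and SNORD21 and SNORA18 by -0.46 and -0.27, none of them past the threshold. Histone genes have near-identical copies, so values of single members are uncertain.

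Genes that fell were fewer and moved less. Of the cholesterol synthesis list, 1 of 18 tested members fell, 5 did when adjusted over the list alone, and the median log2 difference was -0.23. The member that fell was LSS, which makes lanosterol (log2 difference -0.60, SE 0.11, adjusted p = 0.00943). DHCR7, the last enzyme of a branch of the pathway, differed by -0.36 (adjusted p = 0.111), while its other probe fell by 0.50 (adjusted p = 0.0163). The list's camera call (adjusted p = 4.48e-05) was lost at adjusted p = 0.0883 with an estimated correlation. Of the oxidative phosphorylation list, 0 of 27 members passed in limma, also when adjusted over the list alone, with a median of -0.12. Its camera call (adjusted p = 0.00308) was lost at adjusted p = 0.218 with an estimated correlation.

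After NACA4P, the largest falls were in NT5DC2 (-0.98, SE 0.10, adjusted p = 8.7e-05), MTURN (-0.92), CERK (-0.89), SUMF1 (-0.83), TXNDC12 (-0.81) and ACO1 (-0.79). CERK encodes ceramide kinase, SUMF1 the enzyme that activates sulfatases, and ACO1 the cytosolic aconitase that also acts as an iron sensor. The other probe of CERK differed by -0.29 (adjusted p = 0.369). DANCR, UAP1L1, AKAP19, REEP1, RAB4A, CPLX1 and TLE2 fell by 0.59 to 0.68 on the log2 scale. The other probe of UAP1L1 differed by -0.22 (adjusted p = 0.543). When single arrays were left out in turn, 8 to 14 of the 15 genes with the largest falls still passed, and all 15 of those with the largest rises did. The call was lost without 7 of the 8 arrays in turn for AKAP19, without 6 for SUMF1, TXNDC12, REEP1 and CPLX1, without 5 for UAP1L1, and without 1 for RAB4A and TLE2, so the falls of the first 6 are uncertain.

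The lists nearest to the known partners and pathways of CacyBP/SIP did not pass in camera in the reported fit. Each passed in the test of fry for changes in either direction, as did 17 of the 24 lists. With median scaling 9 lists passed in camera, against 7 in the reported fit. For lists near the threshold, such as the Wnt targets, a failure to pass in every fit is therefore not shown. Of 13 tested partners of the protein, 0 passed in limma and 1 fell when adjusted over the list alone; the camera adjusted p was 0.733 (fry in either direction 0.000949). TBL1X, part of a beta-catenin-binding complex, differed by -0.41 (SE 0.10, adjusted p = 0.0727). Of 16 Wnt and beta-catenin targets, 2 rose and 3 did when adjusted over the list alone (camera adjusted p = 0.0643, fry in either direction 0.00211). PLAUR, the urokinase receptor, rose 3.07-fold (log2 difference 1.62, SE 0.16, adjusted p = 8.23e-05), with JUN as the other member, whose call was lost without 6 of the 8 arrays in turn. In the S100 family 0 of 11 passed in limma, also when adjusted over the list alone (camera adjusted p = 0.408, fry in either direction 0.0222). Of the tubulin, actin and cytoskeleton list 0 of 28 passed, also when adjusted over the list alone (camera adjusted p = 0.413, fry in either direction 0.0462). Over all tested probes 2809 had an unadjusted p under 0.05.

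**Figure D3:**
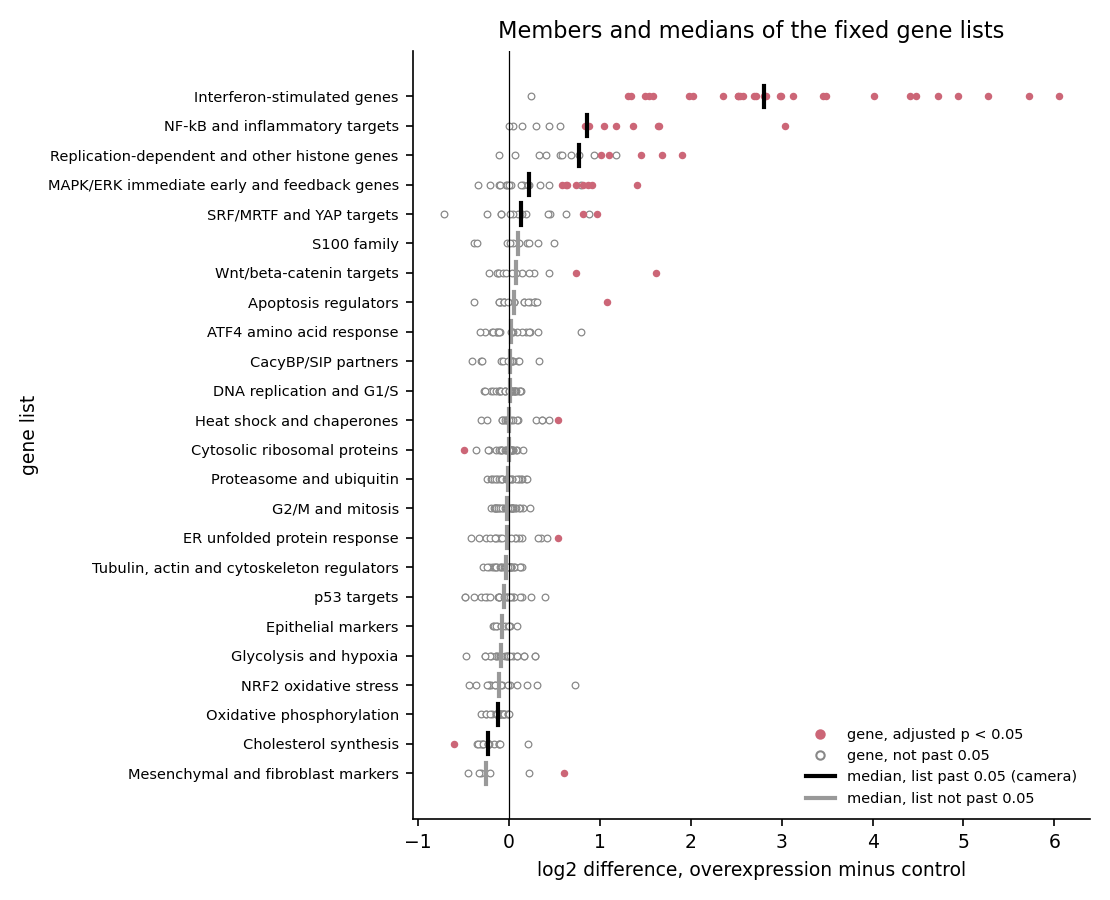
Log2 difference between overexpression and control (horizontal axis) of each tested member of the 24 gene lists tested (vertical axis), filled red where the gene's adjusted p was under 0.05. Vertical bars are list medians, black for the 7 lists past 0.05 in camera and grey for the others; the interferon-stimulated list has its median at 2.80 and the cholesterol synthesis list at -0.23.

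In the reported fit, stress, growth and cell cycle lists did not pass in camera either. Of the apoptosis regulators 1 of 21 rose, the same count as adjusted over the list alone: PMAIP1, which encodes the pro-apoptotic protein NOXA, by 1.08 (SE 0.15, adjusted p = 0.00122; list adjusted p = 0.0708). Of the p53 targets 0 of 23 passed and 1 fell when adjusted over the list alone (0.312). Of the heat shock list 1 of 20 rose, HSPB8 by 0.54, and 2 did when adjusted over the list alone (0.408). Of the unfolded protein response list 1 of 18 rose, XBP1 by 0.53, and adjusted over the list alone 2 rose and 2 fell (0.909). Of the ribosomal protein list 1 of 26 fell, RPS23 by 0.50, the same count as adjusted over the list alone (0.459). The calls of XBP1 and RPS23 were lost without 7 of the 8 arrays in turn, and that of HSPB8 without 6. No member of the DNA replication (31 tested, camera adjusted p = 0.909), mitosis (30, 0.764), ATF4 response (19, 0.909), NRF2 (18, 0.413), glycolysis and hypoxia (25, 0.459) or proteasome (24, 0.909) lists passed in limma, also when adjusted over the list alone. The list median and the camera direction differed in sign for the heat shock, partner, DNA replication and unfolded protein response lists.

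Few markers of cell identity passed. Of 12 epithelial markers 0 passed in limma, also when adjusted over the list alone (camera adjusted p = 0.597), and EPCAM read 12.84 ± 0.13 and 12.85 ± 0.11 (SD, n = 4). The reference genes GAPDH and ACTB differed by -0.14 (adjusted p = 0.592) and 0.02 (adjusted p = 0.956). Of 6 mesenchymal markers SNAI2 rose, at least 1.19-fold, a call lost without 5 of the 8 arrays in turn, and adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.459). Only 4 members each of the remaining 3 lists were tested, too few for a list test. Among colonocyte markers KLF4, a transcription factor, rose 2.97-fold (log2 difference 1.57, SE 0.13, adjusted p = 1.72e-05), the same count of 1 as adjusted over the list alone. Among blood and endothelial markers CD68, a lysosomal protein, rose 2.01-fold (adjusted p = 0.00159), 1 member also when adjusted over the list alone, but its other probes did not pass (0.28 and 0.56). None of the hepatocyte and neural markers passed in limma, also when adjusted over the list alone, with ALB at 0.24 (adjusted p = 0.789).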

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

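The tests of chance for the counts of probes, genes and lists and for the interferon-stimulated median, and the tests of single arrays, of the covariate, of processing, of the plasmids and of the CACYBP probes, were chosen after the results were seen; those of chance for the 6 other list medians were set before their splits were counted, but on lists chosen because they had passed in camera. For the correlation of histone genes the threshold was set before, and the requirement that it hold without 2 arrays was applied after the first value was seen.

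The interferon response is the first pattern. Exchanging samples between the groups argues against chance: of the 35 splits of the 8 arrays, 1 (the real one) gave a median of the interferon-stimulated list as large (2.80, highest other 1.69). No single array carries it, since the lowest median without 1 array was 2.70, nor does the processing, since the lowest over 5 other ways of processing was 2.03. What stays open is a difference between the plasmid preparations or transfections other than the protein, such as DNA amount or contaminants, which may induce interferon by themselves: the design holds 0 groups beyond the 2 plasmids, so this and an effect of the protein cannot be told apart.

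That CACYBP was not higher is the second pattern. A saturated or undetected probe is argued against, because the brighter probe was detected on 8 of 8 arrays and reached at most 8.47% of its array's highest intensity. Probes that lie outside the part of the transcript carried by the plasmid may explain it, and 0 of the CACYBP probes have a target position here, so this and a failed overexpression cannot be told apart.

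The rise of part of the histone list, and of 8 of 146 RNAs without a poly(A) tail, is the third. Chance was not excluded, since 3 of the 35 splits gave a histone median as large (real 0.77, highest other 0.81). For the histone median a single aberrant array is argued against, with a lowest median of 0.58 when 1 array was left out. This does not hold for the RNAs without a poly(A) tail. Of them 2 to 23 rose when 1 array was left out, with a median between -0.03 and 0.09. A varying yield of RNA without a poly(A) tail may contribute: the histone mean followed the mean of those RNAs within groups at Pearson r = 0.78 (exact permutation p = 0.0139, adjusted 0.0278 over 4 relations; Spearman rho 0.524, exact permutation p = 0.188; 8 arrays). The relation rests on control replicate 3 and overexpression replicate 3, without which r was 0.272, so it stays open. In the fit with the mean of those RNAs as a covariate, the histone median was 0.57 and 3 members rose, against 0.77 and 5 without it. That mean covers 146 RNAs that moved unlike, so this fit cannot tell whether any of the rise is apart from RNA yield.

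For the number of probes past the threshold (418, highest other 0), 1 of the 35 splits gave as many. The same held for genes higher (224, highest other 0, 1 of 35) and genes lower (44, highest other 0, 1 of 35). This is the smallest share that 35 splits allow, and it argues against chance for the split as a whole. Splits that mix the groups put the large interferon differences into the spread. Their counts of 0 therefore do not measure how many calls are false, nor exclude chance for the weaker calls or the genes lower. For the number of gene lists chance was not excluded, since 12 of the 35 splits gave as many as 7 (highest other 10). As medians, 1 of the 35 splits was as large for NF-kB targets (0.85, highest other 0.73), cholesterol synthesis (size 0.23, highest other 0.20) and oxidative phosphorylation (size 0.12, highest other 0.09). The share is not adjusted over the 7 medians, and these lists were taken because they passed, so chance was not excluded for them. With an estimated correlation these 3 calls were lost. For MAPK/ERK genes 2 of 35 were (0.21, highest other 0.27), and for SRF and YAP targets 2 of 35 (0.134, highest other 0.136), so chance was not excluded.

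In 24 of 388 groups of 4 arrays, 1 array lay far from the other 3 (gap over range above Dixon's 95% critical value), where chance gives about 19.4. In control, the ratio was 0.979 for UAP1L1, 0.928 for SPRY2, 0.894 for H2AC18, 0.868 for PARP9, 0.853 for ALDOC, 0.847 for GPI, 0.841 for CD68, 0.839 for MAP2, 0.836 for RSAD2, 0.832 for IRF7 and 0.831 for BIRC2. In the arrays labelled overexpression it was 0.952 for EPSTI1, 0.916 for IFI6, 0.915 for CCN1, 0.902 for MAP2, 0.851 for PARP9, 0.836 for COL6A1 and 0.889 for mean intensity. Of the list means in control, it was 0.947 for glycolysis and hypoxia, 0.879 for colonocyte markers, 0.858 for the proteasome, 0.850 for ribosomal proteins, 0.844 for Wnt targets and 0.839 for the unfolded protein response.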

How the results depend on the processing

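The fits without overexpression samples 1 and 3 and with the poly(A) covariate were chosen after seeing the data. The brighter probe of CACYBP kept its sign and stayed above 0.05 in every fit run (-0.32 to -0.10, limma adjusted p 0.31 to 0.774). The dimmer probe differed by -0.33 in the reported fit (limma adjusted p = 0.367). The median of the interferon-stimulated list lay between 2.03 and 2.97, and 29 or 30 of its 31 members rose in the fits that tested 31. Probes past the threshold numbered 705 with array weights and 241 at an adjusted p under 0.01. They numbered 724 without overexpression replicate 3 and 263 to 351 without any other single array. Genes higher were 154 to 338 when 1 array was left out. Genes lower were 88 without background correction, 91 with normexp and an offset of 50, 29 with median scaling, 122 in the authors' table, 108 with array weights, 73 with trend and robust variance, and 12 to 122 when 1 array was left out. With an estimated correlation 1 list passed. The cause was not tested, except that a stricter threshold passes fewer probes. Without overexpression samples 1 and 3, 440 probes passed, with 247 genes higher and 39 lower. With the mean of RNAs without a poly(A) tail as a covariate 354 passed. In that fit the glycolysis and hypoxia list, not past the threshold in the reported fit, reversed to a median of 0.0626 (camera adjusted p = 0.00366). Within groups this list went against the covariate (Pearson r = -0.934), and the covariate was 0.157 higher in overexpression. Adjusting for it therefore raises the list. That relation rests on control replicate 3 and overexpression replicate 3.

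It is open whether the replicate numbers pair the samples. Same-numbered samples deviated together at r = 0.28, 0.05, 0.41 and 0.09, and 7 of 8 samples correlated best with their own number. This is a hint of pairing from the data, and the reported fit uses no pairing. With the replicate block 608 probes passed, with 304 genes higher, 79 lower and 8 lists. Of single named genes, 3013 comparisons with other settings kept their call, 179 lost and 50 gained the threshold. Of the calls of list tests 501 were kept, 7 were lost, 18 were gained and 1 reversed. A gene or list not past the threshold in both fits counted as kept, whatever its sign. Slide as a block was not run, since the sources used here give no slide. Genes undetected in control have bounds only, since signal over background limits their folds, and 5 of the 15 largest rises are not tested when detection on all 8 arrays is required.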

Other observations

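The gene groups here were chosen after the values of single genes were seen, so their tests describe these data only. Genes of antigen presentation by MHC class I were higher in the samples labelled overexpression: 7 of 12 rose, among them TAP1, a peptide transporter (log2 difference 1.47, SE 0.12), and B2M, the shared light chain (1.03, SE 0.10), with HLA-B, HLA-C, HLA-E and HLA-F between 0.76 and 1.05, whose probes can read related HLA genes. The median was 0.81, and 0.61 in the authors' table. The list had an adjusted p of 8.5e-15 in camera and an adjusted p = 0.0175 with an estimated correlation. In the immunoproteasome group 2 of 4 rose, PSMB9 by 2.29 (SE 0.20) and PSME2 by 0.78 (SE 0.13), while PSMB10 differed by -0.03 (adjusted p = 0.931). Of the 3 catalytic subunits of the constitutive proteasome 0 passed in limma. Those subunits differed by -0.20 (PSMB6), -0.04 (PSMB7) and -0.02 (PSMB5), and their median turned from -0.04 to 0.01 with cyclic loess.

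Genes of nucleic acid sensing and its signalling rose in part. Of these 15 genes, which include transcription factors such as IRF7, 8 rose. They were IFIH1, RIGI, IRF7, DHX58 (at least 2.35-fold), EIF2AK2 (log2 difference 1.65), MYD88 (0.90), TLR3 (0.79) and TRIM25 (0.63). STING1, MAVS, TBK1 and IRF3 did not pass, with log2 differences of 0.16, 0.03, -0.03 and 0.07. Of 9 cell death effectors PMAIP1, CASP4 (0.68) and MLKL (0.62) rose, and 1 to 3 did when 1 array was left out (1 without control replicates 3 and 4 and overexpression replicates 2 and 4). Of 9 keratins KRT14, KRT16 (1.45), KRT80 (0.91) and KRT7 (0.67) rose, 2 to 4 when 1 array was left out (2 without control replicates 2, 3 and 4 and overexpression replicates 1, 2 and 4), while KRT8, KRT18 and KRT19, the keratins of simple epithelia, differed by 0.01, -0.07 and -0.01. KRT14 was at least 2.15-fold higher. TLR3, KRT16 and KRT7 were each detected on 1 of 4 control arrays, so their sizes are uncertain. IFIH1, RIGI and IRF7 also belong to the fixed interferon-stimulated list. In camera with an estimated correlation the adjusted p was 0.0175 for the sensing genes and for cell death effectors. It was 0.0334 for keratins and 0.522 for RNAs without a poly(A) tail. Because these groups were chosen after their values were seen, these p-values do not rank them above the fixed lists. The adjustment in these tests ran over 8 groups, of which those with fewer than 5 tested members, such as the immunoproteasome and the constitutive subunits, are too small for a list test.

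Within groups the arrays differed most on an axis that held 42.5% of the variance, with replicate 3 of both groups at an end. Replicate 1 lay farthest toward the opposite end in both groups (-0.24 in control and -0.59 in overexpression). In both groups replicate 3 also had the lowest mean of the NF-kB (-0.19 in control and -0.26 in overexpression, relative to the group mean), MAPK/ERK (-0.10 and -0.13) and SRF and YAP lists (-0.10 and -0.16), as of the histone list and of RNAs without a poly(A) tail (-0.28 and -0.22). The mean of the glycolysis and hypoxia list went against that of RNAs without a poly(A) tail within groups (8 arrays, Pearson r = -0.934, exact permutation p = 0.00868, adjusted 0.0278 over 4 relations; Spearman rho -0.69, exact permutation p = 0.0764). Without control replicate 3 and overexpression replicate 3 r was -0.444, so the relation rests on those arrays. Against log2 mean intensity r was 0.81 (exact permutation p = 0.0642; Spearman rho 0.643, exact permutation p = 0.101) and 0.257 without overexpression replicates 1 and 3. The interferon-stimulated list gave r = -0.362 against RNAs without a poly(A) tail (exact permutation p = 0.349; Spearman rho -0.571, exact permutation p = 0.125).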
